A study of Mus musculus with 22 samples.

How the data were processed

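RNA was sequenced from 22 pools of whole mouse embryos of the C57BL/6 background that carried a doxycycline-inducible Oct4 or Nanog transgene. Per the labels' protocols, mothers of the E7.5 induced pools received doxycycline by intraperitoneal injection at E4.5 and then in the drinking water, and mothers of the E9.5 induced pools received it in the water from E6.5; controls received none. Pools held 8 to 12 embryos at E7.5 and 3 at E9.5, so the replicates are pools of embryos, not single embryos. The protocols name 2 sequencers and do not state which of them read each library, nor whether the libraries keep strand. A difference between sequencing batches is therefore not separated from the groups, including the fold changes of Nanog E7.5 and Nanog E9.5.

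The deposited table holds RSEM expected counts per gene and library, which the authors did not normalize or filter, as far as the values show. Library totals differ, and genes at 0 in every library are kept. Of all values of a library, those at 0 included, 12.8% to 21.4% are not whole numbers. Per the submitters' processing notes, RSEM 1.17, cutadapt, Picard and limma were used with the mouse genome build NCBIM37. RSEM divides reads that fit several genes between them, so values of pseudogenes, close paralogs, globins and other genes that share reads are uncertain, as are genes that overlap or run antisense to another gene. A transgene read cannot be told from a read of the endogenous Pou5f1 or Nanog gene in these counts. Of the 37680 gene IDs, 37309 were found in the GENCODE mouse annotation of release 1 (Ensembl release 65), which gave symbols, coordinates, exonic length and GC content.

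Groups followed the labels: transgene, stage and doxycycline. Totals ran from 4.72 to 42.3 M counts per library and the number of genes detected from 17771 to 21262. A floor of 3 counts, the upper limit that a count of 0 allows, was 0.0709 to 0.636 CPM per library; intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A fold change against a group at 0 is given as a lower bound, against 3 counts over the whole group. A check for libraries that are copies of one another gave chi-square values per degree of freedom of 1.6 to 67.1 over 20 pairs within groups, for genes with at least 20 summed counts.

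Each induction was tested on its own groups with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, on counts rounded to whole numbers, with TMM scaling, the filterByExpr filter and robust dispersions. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Every adjusted p printed for a gene comes from this test unless another tool is named. Differences between inductions were tested as interaction contrasts over 4 groups, and the E9.5 and E7.5 controls of each line were compared with the same test. Levels are CPM (counts scaled to a common library size, mean ± SD over pools), fold changes are on the log2 scale with their standard error (SE), and n is the number of pools.

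A total of 26 gene lists with 505 members was fixed; 496 members matched 1 gene ID, 6 were divided over 2 gene models of the same symbol (among them Pou3f1, Hoxa3, Alx1, Trf and Dab2) and were left out of the lists, and 3 (Ahsp, Sox1 and Rhox5) were not matched. Pou5f1 and Nanog are in no list. Results of some genes are not reported here. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 104 tests of 26 lists and 4 inductions; the 104 list tests of the interactions form another family. Camera was repeated with a correlation estimated from the data, and fry was run as a self-contained test. Within each list, members are counted as called over all genes tested and adjusted over the list alone. With the preset correlation 49 of the 104 tests passed, with an estimated correlation 0 did, and fry passed 35 and camera on limma-voom values 52. In 10 tests, none of which passed, the median, the mean and the test of a list differed in sign. In 1 list a member was at 0 in a group (Hoxc5 in the Hox list of Oct4 E7.5), and its bound left the list median at -2.36.

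Named genes followed a rule: Pou5f1 and Nanog; per induction the 12 highest and 12 lowest fold changes among called genes with a mean of at least 5 CPM in the higher group, a named symbol and no overlap between control and induced libraries, a separation that chance alone gives to 10% of genes with 3 pools against 3; up to 4 members per list with the lowest p, and any member of the Hox, primitive haematopoiesis and core pluripotency lists; the 5 largest differences per interaction; the 5 highest and 5 lowest genes of each stage comparison; and genes named by size that were called in both of the inductions compared. Where 5 or fewer members of a list were called in a direction all are named; those that fall outside the rule were chosen after their values were seen. Pairs of inductions were compared by the number of genes called in both, against the number for independent lists, with Fisher's exact test (one-sided), and by the correlation of fold changes across genes; the 4 inductions share no library, and genes are not independent replicates. Each induction was also set against the stage difference between controls of the other line.

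The groups, tests, lists, naming rule and the following alternatives were chosen before the data were examined: DESeq2 1.42.0, limma-voom, size factors of the RLE type, no filter on low counts, 1 model over all 22 libraries, each replicate left out in turn, a block for shared replicate numbers, unrounded counts, and library sizes without 50 mitochondrially encoded and globin genes. Chosen after seeing the data were a GC offset per library (loess span 0.3), libraries thinned to the smallest of a comparison (seed 5), the 22051 protein-coding models of at least 300 nucleotides, counts summed over IDs that share a symbol, and the Oct4 line controls in place of the Nanog line controls. No scaling alternative moved the median fold change of all genes by 0.1 or more. Whether equal replicate numbers pair the pools was checked from correlations of deviations from the group means: in Oct4 E7.5, control and induced pools with the same number gave 0.386, 0.411 and 0.135, so these numbers were treated as pairs, from the data and not from the labels, and the fit with the replicate block is given where it changes a call.

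The tests were tried on simulated data: counts drawn for the real genes and library sizes with 200 genes changed 1.5-fold, 2-fold or 4-fold (seed 11). The test of Oct4 E7.5 (16071 genes) recovered 52.2%, 65.7% and 87.9% of them at these folds, that of Nanog E7.5 (14118 genes) 17.9%, 53.7% and 84.8%, that of Oct4 E9.5 (13957 genes) 62.7%, 88.1% and 93.9%, and that of Nanog E9.5 (13305 genes) 70.1%, 86.6% and 98.5%. Unchanged genes made up 17 of 154, 15 of 119, 14 of 177 and 20 of 190 calls. Interactions recovered fewer: 10.4%, 41.8% and 66.7% between lines at E7.5, 43.3%, 64.2% and 87.9% at E9.5, 8.96%, 56.7% and 80.3% between stages for Oct4 and 11.9%, 49.3% and 63.6% for Nanog. Among 20 unchanged simulated lists per induction, camera gave a p under 0.05 for 0, 0, 0 and 1. The simulated genes were drawn independently of one another. These lists therefore cannot show whether the preset correlation is adequate for real lists, whose members may vary together. No sample and no column was left out.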

Results

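RNA of whole mouse embryos was sequenced from 22 pools that carried a doxycycline-inducible Oct4 or Nanog transgene, at E7.5 and at E9.5, with doxycycline (induced) or without it (control). Oct4 E7.5 had 3 control pools (29.4, 39.6 and 42.3 M counts for replicates 1 to 3) and 3 induced pools (40.1, 35.2 and 24.9 M). Nanog E7.5 had 2 control pools (replicates 2 and 3, 6.59 and 8.54 M) and 3 induced pools (replicates 1, 3 and 4, 10.9, 26.0 and 6.95 M). Oct4 E9.5 had 3 control pools (8.97, 14.2 and 7.72 M) and 3 induced pools (replicates 3 to 5, 10.4, 4.72 and 8.28 M). Nanog E9.5 had 2 control pools (replicates 2 and 3, 15.8 and 15.7 M) and 3 induced pools (4.77, 5.63 and 5.15 M). None of the 8 groups received doxycycline without a transgene.

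Pou5f1, the gene of the pluripotency factor Oct4 (chr 17, 35642982 to 35647721, NCBIM37), was still abundant in E7.5 controls and close to absent from E9.5 controls. In the Oct4 line at E7.5 it rose from 243 ± 20.5 to 622 ± 90.3 CPM (log2 fold change 1.38 ± 0.11 SE, adjusted p = 0.00037). At E9.5 it rose from 0.814 ± 0.406 to 245 ± 11.8 CPM (8.39 ± 0.12, adjusted p = 8.02e-15). In the Nanog line Pou5f1 rose at E7.5 from 231 ± 16.2 to 544 ± 72.1 CPM (1.22 ± 0.12, adjusted p = 0.000955) and read 0.956 ± 0.0432 and 1.198 ± 0.607 CPM in controls and induced pools at E9.5. Nanog, the gene of the other induced pluripotency factor (chr 6, 122657507 to 122664651), rose in the Nanog line at E9.5 from 2.13 ± 0.219 to 324 ± 3.37 CPM (7.27 ± 0.10, adjusted p = 1.4e-18). In that line at E7.5 it read 19.8 ± 3.94 and 93.7 ± 30.9 CPM (2.24 ± 0.45), with no overlap between 2 and 3 pools, a separation that chance gives to 20% of genes. It did not pass the test (adjusted p = 0.0752). In the Oct4 line Nanog rose at E7.5 from 20.5 ± 1.77 to 31.0 ± 5.53 CPM (0.62 ± 0.14, adjusted p = 0.0272), a call lost without control 1 (0.0699), control 2 (0.104) or control 3 (0.134). At E9.5 it read 0.813 ± 0.353 and 1.06 ± 0.236 CPM. Transgene and endogenous transcripts are counted together.

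**Figure D1:**
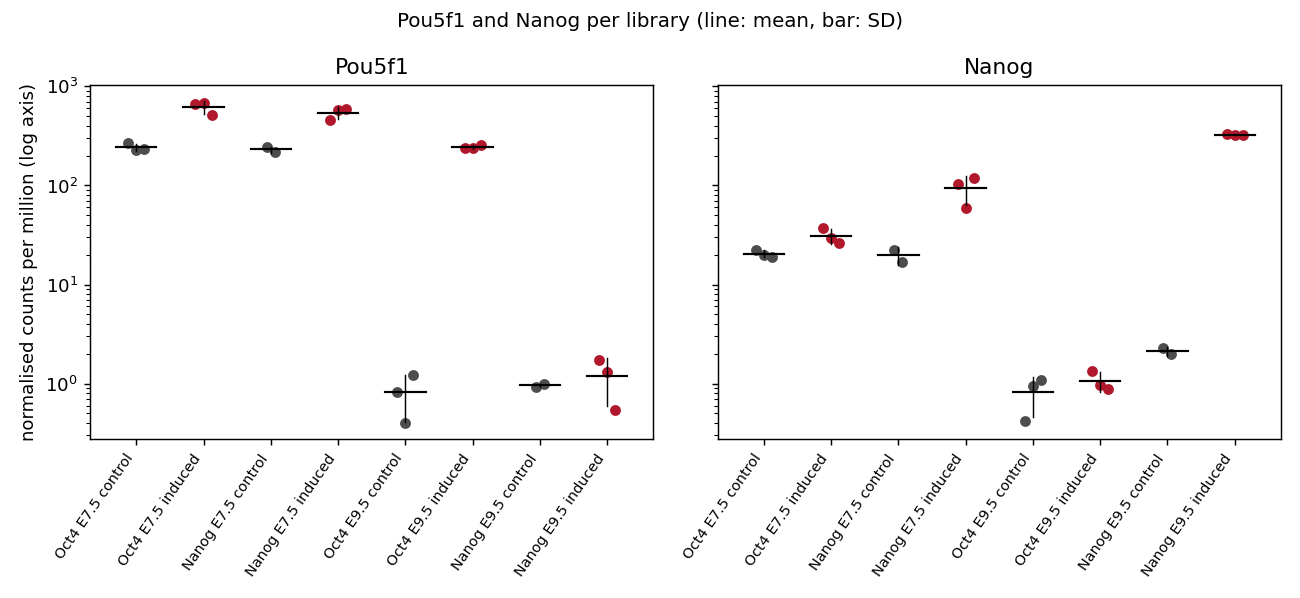
Levels of Pou5f1 and Nanog in counts per M (CPM, log axis) in the 8 groups. Each point is 1 pool (grey control, red induced), the line is the mean and the bar the SD; both genes were already expressed in E7.5 controls, and at E9.5 each had a mean of 0.813 to 2.13 CPM outside the induced pools of its own line.

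Oct4 induction at E7.5 came with lower Hox, primitive haematopoiesis, endothelium and heart lists and higher primed epiblast and core pluripotency lists, none of which passed with an estimated correlation (adjusted p = 0.0685 to 0.139). Hbb-bh1, an embryonic beta globin (chr 7, 110990150 to 110991678), fell from 78.3 ± 31.4 to 1.27 ± 0.429 CPM (log2 fold change -5.98 ± 0.39, adjusted p = 0.000378). Aldh1a2, which makes retinoic acid (chr 9, 71063596 to 71144050), fell from 131 ± 37.8 to 7.17 ± 0.703 CPM (-4.16 ± 0.24, adjusted p = 0.000181). Eomes, a T-box factor of the early streak and definitive endoderm (chr 9, 118387330 to 118395250), rose from 40.1 ± 5.84 to 203 ± 48.3 CPM (2.36 ± 0.18, adjusted p = 0.000297). Nodal, the ligand that patterns the epiblast, rose from 2.05 ± 0.21 to 13.3 ± 3.08 CPM (2.72 ± 0.20). Among the largest changes with no overlap between 3 and 3 pools, a separation that chance gives to 10% of genes, were the T-box gene Tbx4 (-4.45 ± 0.27), the somite gene Meox1 (-4.60 ± 0.29) and Arg1, which encodes arginase (-4.22 ± 0.30). Hes3 (-6.76 ± 0.47) and Shh (-3.80 ± 0.27) fell, and Foxd3 (5.81 ± 0.45), C1ql2 (3.77 ± 0.24) and Fgf5 (3.07 ± 0.36) rose. The edgeR test called 991 of 16071 genes, 362 higher and 629 lower, and 173 and 388 of these by at least 2-fold. The count was 504 without control 1, 438 without control 3, 584 without induced 3 and 1638 with 1 model over all 22 libraries. Of the 24 genes named by size, 21 kept their call in every fit without 1 library.

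Hox genes, which set position along the body axis, fell as a group in Oct4 E7.5: 23 of 30 measured members fell and 0 rose (26 and 0 adjusted over the list alone), with a median log2 fold change of -2.36. Of the 23, 21 kept their call in every fit without 1 library. Hoxb9 fell by -3.23 ± 0.25, Hoxb6 from 9.75 to 1.24 CPM and Hoxb1 from 69.8 to 22.4 CPM, while Hoxc5 went from 0.439 CPM to 0 (at least 13-fold lower). The camera test of the list gave adjusted p = 4.47e-55, and adjusted p = 0.0685 with an estimated correlation. Of 25 primitive haematopoiesis genes 17 fell and 0 rose (20 and 0 adjusted over the list alone). The haematopoiesis list had a median log2 fold change of -1.12, adjusted p = 1.41e-41, and adjusted p = 0.08 with an estimated correlation. They included the erythroid factor Klf1 (4.41 to 0.417 CPM, -3.40 ± 0.26) and the blood and endothelial factor Tal1 (39.0 to 11.7 CPM, -1.72 ± 0.16). Gata1 fell too (-1.12 ± 0.23), a call lost without control 3 (adjusted p = 0.0855). Of 16 endothelial genes 9 fell and 0 rose (11 and 0 adjusted over the list alone), among them the receptor gene Tek (13.5 to 3.84 CPM) and VE-cadherin, Cdh5 (14.7 to 4.86 CPM). The endothelium list had adjusted p = 8.4e-16, and adjusted p = 0.0685 with an estimated correlation.

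Of 14 primed epiblast genes 9 rose and 0 fell in Oct4 E7.5 (10 and 2 adjusted over the list alone): Fgf5 from 3.88 ± 1.66 to 32.1 ± 11.1 CPM, Zic5 by 1.07 and Pim2 by 1.45 ± 0.16. The primed epiblast list had adjusted p = 1.64e-19, and adjusted p = 0.139 with an estimated correlation. Of 21 core and naive pluripotency genes 6 rose and 0 fell (9 and 0 adjusted over the list alone), with Utf1 at 31.7 and 82.7 CPM (1.41 ± 0.08), Esrrb at 15.7 and 36.6 CPM (1.25 ± 0.17) and Nr0b1 1.38 ± 0.19. The core pluripotency list had adjusted p = 9.98e-07, and adjusted p = 0.0965 with an estimated correlation. The coreceptor gene Tdgf1 went from 4.22 ± 3.8 to 145 ± 42.7 CPM (5.10 ± 0.69, adjusted p = 0.0183), a call lost without control 3 (0.085), induced 1 (0.0864) or induced 2 (0.0765). The streak and nascent mesoderm list moved both ways, with 10 of 22 members higher and 8 lower (10 and 8 adjusted over the list alone, adjusted p = 0.243). Besides Eomes, Mesp1 (10.7 to 58.5 CPM), Wnt3 (3.60 to 20.7 CPM) and Lhx1 (13.7 to 77.0 CPM) rose. The posterior genes Cdx1 (117 ± 42.4 to 9.27 ± 1.16 CPM), Msgn1 (20.3 to 2.15 CPM) and Cdx4 (-2.65 ± 0.23) fell. Of 14 paraxial mesoderm genes 3 rose (Lfng, Dll3 and Mesp2, 2.20 ± 0.24) and 5 fell, Meox1, Aldh1a2, Tcf15, Pax9 and Hes7 (3 and 8 adjusted over the list alone). The somite list had adjusted p = 7.01e-06, and adjusted p = 0.139 with an estimated correlation. Lfng had 0.11 without control 3 and Hes7 0.0907 without control 1. Of 23 heart genes 10 fell and Myl7 rose (2 higher and 11 lower adjusted over the list alone), with Tbx5 at -3.50 ± 0.44 and Myh7 at -2.22. The heart list had adjusted p = 2.9e-10, and adjusted p = 0.139 with an estimated correlation. Of 14 retinoic acid pathway genes 4 fell, Aldh1a2, Rarb (-2.33 ± 0.27), Crabp2 (51.8 to 10.2 CPM) and Crabp1 (1 higher and 7 lower adjusted over the list alone). The retinoic acid list had adjusted p = 2.78e-11, and adjusted p = 0.173 with an estimated correlation.

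Other lists passed in Oct4 E7.5 as well. In the integrated stress response list 5 of 21 rose, the amino acid transporters Slc7a3 (23.7 to 95.6 CPM), Slc7a11 and Slc7a5, with Asns and Cth (9 higher and 1 lower adjusted over the list alone). The stress response list had adjusted p = 1e-06, and adjusted p = 0.203 with an estimated correlation. Of 12 neural crest genes Foxd3 rose and Prrx1, Prrx2, Snai2 and Alx4 fell (1 and 6 adjusted over the list alone). The neural crest list had adjusted p = 0.000912, and adjusted p = 0.478 with an estimated correlation. Of 17 node and endoderm genes Trh, Foxj1, Chrd, Cer1 (27.1 to 59.8 CPM) and Lefty1 rose and Shh fell (7 and 2 adjusted over the list alone). The node and endoderm list had adjusted p = 0.0408, and adjusted p = 0.553 with an estimated correlation. In the p53 target list Pmaip1, an inducer of cell death, rose from 26.0 to 94.1 CPM, 1 of 18 members (1 adjusted over the list alone). The p53 target list had adjusted p = 0.0389, and adjusted p = 0.46 with an estimated correlation. Plat and Lama1 fell among 10 parietal endoderm genes (0 higher and 4 lower adjusted over the list alone). The parietal endoderm list had adjusted p = 3.62e-05, and adjusted p = 0.302 with an estimated correlation. Dlx3 fell among 15 trophoblast genes (0 and 2 adjusted over the list alone), whose list had adjusted p = 0.0462, and adjusted p = 0.632 with an estimated correlation. Prf1 and S100a9, of killer cells and neutrophils, rose among 15 maternal decidua and blood genes (4 and 1 adjusted over the list alone). The maternal list had adjusted p = 0.0449, and adjusted p = 0.575 with an estimated correlation. Of these, Lefty1 lost its call without control 3 (0.0732) or induced 1 (0.0642), Slc7a5 and Asns without control 3 (0.161 and 0.152), Chrd and Alx4 without control 3 (0.0686 and 0.0958), Lama1 without induced 3 (0.174), Prf1 without control 1 (0.0593) and S100a9 without control 3 (0.177). The maternal, node and p53 calls were also lost with limma-voom.

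Other lists did not pass in Oct4 E7.5, and their called genes are named. Of 12 anterior neural plate genes Otx1 and Otx2 were higher and Six3, Hesx1, Lhx2, Lhx5 and Foxd4 lower (4 and 7 adjusted over the list alone, adjusted p = 0.0523). Foxd4 alone kept its call in every fit without 1 library, and the others had up to 0.156 (Otx1) without control 3. Of 14 neuronal differentiation genes Dcx was higher and Isl1, Mnx1, Ebf2 and Ebf3 lower (3 and 4 adjusted over the list alone, adjusted p = 0.09), with 3 of the 5 calls kept and up to 0.177 for Ebf2 without control 1. With the replicate block Otx1 (0.0509), Ebf2 (0.0734) and Ebf3 (0.0521) lost their calls. Of 10 Wnt feedback targets Sp5 and Dkk1 were higher and Notum lower (3 and 2 adjusted over the list alone, adjusted p = 0.552), with Sp5 and Notum kept and 0.152 for Dkk1 without control 3. Of 21 hypoxia and glycolysis genes Pdk1 and Bnip3 were higher and Slc2a1, Slc2a3, Vegfa and P4ha2 lower (3 and 4 adjusted over the list alone, adjusted p = 0.51), with 1 of 6 kept, Pdk1. Of 9 primordial germ cell genes 0 rose and Kit and Ifitm3 fell (0 and 3 adjusted over the list alone), with adjusted p = 0.0579 for the list and 0.0286 with the replicate block. Of 18 visceral endoderm genes 0 rose and Lrp2 fell (0 and 1 adjusted over the list alone), with adjusted p = 0.0907 for the list and 0.0361 with the replicate block. Kit lost its call without control 1 (0.0864), Ifitm3 without control 3 (0.211) and Lrp2 without induced 3 (0.0871). With edgeR 0 members were called, over all genes or adjusted over the list alone, in the nuclear respiratory chain (25 tested, adjusted p = 0.109), immediate early (11 tested, 0.555), cell cycle (27 tested, 0.595) and mitochondrially encoded (13 tested, 0.869) lists.

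Nanog induction at E7.5 was followed by a higher primed epiblast list and lower primitive haematopoiesis, Hox, somite and visceral endoderm lists, and with an estimated correlation none of these passed (adjusted p = 0.0685 to 0.212). Fgf5, a growth factor of the primed epiblast (chr 5, 98683203 to 98706049), rose from 4.13 ± 0.117 to 68.8 ± 8.27 CPM (log2 4.04 ± 0.17, adjusted p = 1.25e-05). Eomes rose from 28.3 to 267 CPM (3.22 ± 0.19, adjusted p = 0.000264). Nodal rose from 1.69 to 15.2 CPM (3.17 ± 0.34) and its inhibitor Lefty2 from 9.14 to 55.1 CPM (2.60 ± 0.24). Hbb-bh1 fell from 54.4 to 0.866 CPM (-6.04 ± 0.36, adjusted p = 0.000528), Meox1 by -4.45 ± 0.26, Arg1 from 18.5 to 0.617 CPM (-4.88 ± 0.28) and Tbx4 by -5.14 ± 0.33. Other large increases were Pmepa1 (3.32 ± 0.38), Mmp25 (3.01 ± 0.35) and Slc35d3 (2.77 ± 0.31); mt-Te and mt-Ts1, mitochondrial tRNA genes of short length, and the pseudogene Eif5al3-ps also fell, with uncertain values. The edgeR test called 1099 of 14118 genes, 418 higher and 681 lower, 196 and 320 of them by at least 2-fold. The count was 161 without control 2, 171 without control 3, where the lone control is assumed to vary like the induced pools. It was 1721 without a filter on low counts, 2737 with 1 model over all libraries and 3744 against the Oct4 line controls. Of the 24 genes named by size, 14 kept their call in every fit without 1 library. Reads of gene models under 80 nucleotides took 31.3 to 36.8 CPM in these controls and 0.575 to 1.13 CPM in the induced pools, against 29 to 51.9 CPM in all pools of Oct4 E7.5, so the induced libraries stood apart from the other E7.5 libraries, and mitochondrially encoded genes 3.3% to 3.63% and 5.27% to 8.26% of counts.

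Of 14 primed epiblast genes 9 rose and 0 fell in Nanog E7.5 (9 and 0 adjusted over the list alone), among them Dnmt3b (683 to 1571 CPM), Otx2 (49.8 to 105.5 CPM) and Pim2 (1.81). The primed epiblast list had adjusted p = 3.04e-25, and adjusted p = 0.0685 with an estimated correlation. Of 18 core and naive pluripotency genes 5 rose, Zfp42, Esrrb (1.42 ± 0.18), Dppa5a, Dppa4 and Tdgf1, and Tcfcp2l1 and Lin28a fell (9 and 3 adjusted over the list alone). The core pluripotency list had adjusted p = 0.000413, and adjusted p = 0.145 with an estimated correlation, and 0.0684 against the Oct4 line controls. Tdgf1 went from 3.30 to 228 CPM (6.13 ± 0.58) and Lin28a from 1138 to 776 CPM, and both lost their call in fits without control 2 or control 3. Of the 7 called genes 1 kept its call in every fit without 1 library. Of 24 primitive haematopoiesis genes 13 fell and 0 rose (2 higher and 15 lower adjusted over the list alone), with Lmo2 at -1.80. Lmo2 and Hbb-bh1 kept their call in every fit without 1 library, and others lost it without control 2 or control 3, as Klf1 (-3.66, adjusted p up to 0.13) and Tal1 (-2.24 ± 0.31, up to 0.0897). The haematopoiesis list had adjusted p = 3.7e-20, and adjusted p = 0.139 with an estimated correlation. Of 24 Hox genes 12 fell and 0 rose (1 higher and 16 lower adjusted over the list alone), and Hoxb6 (-3.00 ± 0.38) and Hoxb4 kept their call in every fit without 1 library. The Hox list had adjusted p = 4.44e-13, and adjusted p = 0.08 with an estimated correlation.

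Visceral endoderm and yolk sac genes fell together in Nanog E7.5: 12 of 18 fell and 0 rose (17 lower adjusted over the list alone), with a median log2 fold change of -0.939. The endocytic receptor gene Lrp2 fell from 264 to 97.7 CPM (-1.45 ± 0.16), a call kept in every fit without 1 library. The apolipoprotein gene Apoa1 (542 to 341 CPM, -0.69 ± 0.11) and the factor gene Hnf4a (-0.75) fell as well. Without control 2 or control 3 the adjusted p were up to 0.112 for Apoa1 and up to 0.098 for Hnf4a. The list had adjusted p = 2.79e-16, and adjusted p = 0.212 with an estimated correlation. All 13 mitochondrially encoded genes tested were higher adjusted over the list alone and 10 over all genes (adjusted p = 1.63e-16, adjusted p = 0.25 with an estimated correlation), with mt-Co3 at 3551 and 7704 CPM (1.10 ± 0.19). None of the 10 kept its call in every fit without 1 library (up to 0.14 for mt-Co3, without control 2), and with a GC offset 0 of the 10 were called, although the list median stayed at 1.02 (1.01 without it) and the list passed (adjusted p = 5.54e-08). Against the Oct4 line controls the median was 0.408 and 1 gene was called.

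Of 11 paraxial mesoderm genes 5 fell in Nanog E7.5, Meox1, Aldh1a2, Pax9, Tcf15 and Foxc1, and Mesp2 rose (2 higher and 7 lower adjusted over the list alone). The somite list had adjusted p = 7.22e-08, and adjusted p = 0.11 with an estimated correlation. Meox1 alone kept its call in every fit without 1 library, and Aldh1a2 and Pax9 had 0.247 and 0.219 without control 2 and Mesp2 0.345 without control 3. Of 21 heart genes 6 fell and 0 rose, among them Mef2c (-2.12), which kept its call without any 1 library (0 higher and 7 lower adjusted over the list alone). The heart list had adjusted p = 3.37e-05, and adjusted p = 0.251 with an estimated correlation. Of 13 retinoic acid genes 4 fell, including Rarb (-2.71) and Crabp1 (-1.81), and Cyp26a1, which degrades retinoic acid, rose (1 and 6 adjusted over the list alone). The retinoic acid list had adjusted p = 0.000182, and adjusted p = 0.213 with an estimated correlation. In the integrated stress response list Mthfd2, Slc7a5, Asns and Slc7a3 (2.07 ± 0.12) rose and Ddit4 fell, of 20 (8 and 1 adjusted over the list alone), and Slc7a3 alone kept its call in every fit without 1 library, with up to 0.373 for Slc7a5 without control 2. The stress response list had adjusted p = 0.00029, and adjusted p = 0.429 with an estimated correlation. Perp (1.08) and Pmaip1 (1.94 ± 0.15) rose among 18 p53 targets (5 and 0 adjusted over the list alone). The p53 target list had adjusted p = 0.00251, and adjusted p = 0.173 with an estimated correlation, and 0.0811 against the Oct4 line controls. Elf5 rose (1.47 ± 0.19) and Esx1 fell (-1.83) among 15 trophoblast genes (1 and 1 adjusted over the list alone), with 0.0541 for Elf5 and 0.168 for Esx1 without control 2. The trophoblast list had adjusted p = 0.00156, and adjusted p = 0.503 with an estimated correlation. The immediate early genes Zfp36, Ier3 and Fos (1.53 ± 0.27) rose, of 11 (4 and 0 adjusted over the list alone). None of these 3 kept its call in every fit without 1 library, and Fos lost it without control 2 or control 3. The immediate early list had adjusted p = 0.00279, and adjusted p = 0.347 with an estimated correlation. Of 11 neural crest genes Foxd3 rose and Snai2, Alx4, Prrx1 and Twist1 fell (1 and 5 adjusted over the list alone), and none of these 5 kept its call without control 2 or control 3, as for Foxd3 (0.113 and 0.123). The neural crest list had adjusted p = 0.00333, and adjusted p = 0.187 with an estimated correlation, and 0.109 against the Oct4 line controls.

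Among lists that did not pass in Nanog E7.5, the streak and nascent mesoderm list had 6 of 22 genes higher and Wnt3a, Wnt8a, Tbx6, Cdx1 and Cdx2 lower (9 and 7 adjusted over the list alone, adjusted p = 0.243). Within it Mesp1 (2.36 ± 0.14) and Wnt3 (2.64 ± 0.22) rose and Wnt8a (-1.48) fell in every fit without 1 library. Of 16 node and endoderm genes Chrd, Cer1, Lefty1 and Lefty2 were higher and 3, among them Foxa1 and Shh, lower (6 and 3 adjusted over the list alone, adjusted p = 0.178), and Lefty2 alone kept its call in every such fit. Of 16 endothelial genes Tek, Sox7 and Ramp2 were lower (0 and 4 adjusted over the list alone, adjusted p = 0.164), with Tek (-2.14 ± 0.25) kept. Of 20 hypoxia and glycolysis genes Ndrg1 was higher and Slc2a1, Slc2a3, Eno1 and Vegfa lower (2 and 4 adjusted over the list alone, adjusted p = 0.586), with Slc2a3, a glucose transporter (2585 to 1255 CPM), kept. Of 8 anterior neural plate genes Otx2 was higher, a call kept in every fit, and Foxd4 lower (1 and 4 adjusted over the list alone, adjusted p = 0.255). In 4 lists no call was kept in every fit without 1 library: parietal endoderm (Plat and Lamb1 lower of 10, 0 and 3 adjusted over the list alone, adjusted p = 0.0782), Wnt feedback (Dkk1 higher, Axin2 and Rnf43 lower of 10, 1 and 4 adjusted over the list alone, 0.13), neuronal (Elavl3 higher, Isl1 and Mnx1 lower of 9, 3 and 4 adjusted over the list alone, 0.469) and primordial germ cell (Kit lower of 6, 0 and 1 adjusted over the list alone, 0.805). With edgeR 0 members were called in the nuclear respiratory chain (25 tested, adjusted p = 0.0502, and 0.0483 with the replicate block of Oct4 E7.5 in the same family of tests), cell cycle (27 tested, 0.164) and maternal decidua (14 tested, 0.789) lists.

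**Figure D2:**
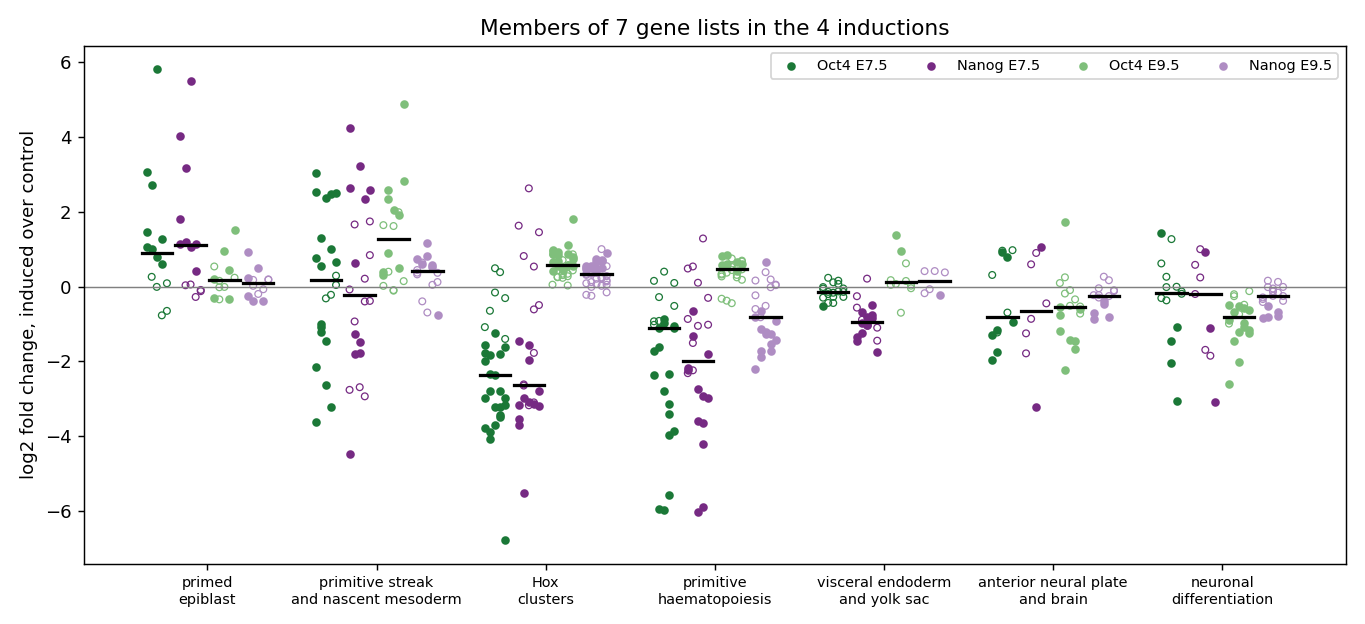
Log2 fold change (induced over control) of the members of 7 gene lists in the 4 inductions. Each point is 1 gene, filled where the edgeR adjusted p was under 0.05 and open where not, and the black line is the list median; in Oct4 and Nanog E7.5, 28 of 30 and 19 of 24 Hox members and 22 of 25 and 20 of 24 primitive haematopoiesis members lay below 0, and the lowest Hox point, Hoxc5 in Oct4 E7.5, is a fitted value against a group at 0.

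Oct4 induction at E9.5 gave higher streak and Hox lists and lower neuronal and anterior neural lists, calls lost with an estimated correlation (adjusted p = 0.1 to 0.139). Olig2, a factor of motor neuron and oligodendrocyte progenitors (chr 16, 91225795 to 91228922), fell from 13.6 ± 0.201 to 2.18 ± 0.312 CPM (log2 -2.60 ± 0.17, adjusted p = 1.91e-08). Nkx2-1, of the ventral forebrain, thyroid and lung, fell by -2.01 ± 0.25, and Six6, of the eye and hypothalamus, by -2.23 ± 0.26. Wnt8a, a Wnt ligand of the streak (chr 18, 34701967 to 34707927), rose from 0.486 ± 0.139 to 13.8 ± 1.05 CPM (4.89 ± 0.24, adjusted p = 2.92e-10). Cdx1, a caudal homeobox gene (chr 18, 61178516 to 61195853), rose from 3.582 to 22.01 CPM (2.58 ± 0.16). Other large changes were higher Tmem229b (2.36 ± 0.13), Ephx2 (3.08 ± 0.22) and the hindbrain factor Egr2 (3.43 ± 0.36). Lower were Nr2e1 (-2.25 ± 0.19), Dmbx1 (-2.12 ± 0.20), Pou3f2 (-1.92 ± 0.19), Pou3f4 (-2.04 ± 0.24) and Aldh1a3 (-1.96 ± 0.20). The edgeR test called 1297 of 13957 genes, 654 higher and 643 lower, 103 and 95 of them by at least 2-fold. DESeq2 called 599 and 1 model over all 22 libraries 312, and without control 2, induced 3 or induced 5 the count was 625, 742 or 733. Of the 24 genes named by size, 19 kept their call in every fit without 1 library.

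Of 20 neuronal differentiation genes 14 fell and 0 rose (18 lower adjusted over the list alone) in Oct4 E9.5, among them the RNA-binding protein genes Elavl3 (25.1 to 10.9 CPM, -1.21 ± 0.12) and Elavl4 (-1.08) and the basic helix-loop-helix gene Nhlh2 (-2.02 ± 0.21). The neuronal list had adjusted p = 6.23e-29, and adjusted p = 0.11 with an estimated correlation. Of 17 anterior neural plate and brain genes 8 fell, with Otx1 at -1.44 and En2 at -1.19, and Hesx1 rose (1 and 9 adjusted over the list alone). The anterior neural list had adjusted p = 1.02e-09, and adjusted p = 0.139 with an estimated correlation. Of 18 streak genes 10 rose and 0 fell (14 higher adjusted over the list alone), with Msgn1 at 2.83 ± 0.29 and Tbx6 at 1.93 ± 0.22 beside Wnt8a and Cdx1. The streak list had adjusted p = 9.68e-23, and adjusted p = 0.1 with an estimated correlation. Of 34 Hox genes 21 rose and 0 fell (24 higher adjusted over the list alone): Hoxa7 by 0.88 and Hoxb1 from 16.4 to 31.9 CPM. Of the 21, 12 kept their call in every fit without 1 library. Hoxb1 lost its call with 1 model over all libraries (adjusted p = 0.304), and Hoxb9 (0.57 ± 0.10) without control 3 (0.0753). The Hox list had adjusted p = 1.16e-23, and adjusted p = 0.139 with an estimated correlation. Of 26 primitive haematopoiesis genes 7 rose and 0 fell (16 higher adjusted over the list alone). Alas2, of haem synthesis (52.6 to 78.5 CPM, 0.59 ± 0.08), kept its call without each library, whereas Klf1 (0.65 ± 0.15) lost it without induced 3 (0.0621). The haematopoiesis list had adjusted p = 4.82e-10, and adjusted p = 0.178 with an estimated correlation. The adult beta globins Hbb-b1 (25.7 to 116 CPM, 2.17 ± 0.29) and Hbb-b2 (1.08 ± 0.25), which share reads, rose, 2 of 3 maternal blood genes (3 adjusted over the list alone), with 0.0927 for Hbb-b1 without induced 3 and 0.183 for Hbb-b2 without control 2. The maternal blood list had adjusted p = 3e-04, and adjusted p = 0.139 with an estimated correlation.

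Of 24 heart genes Hand2, Gata6 (0.56) and Hand1 (0.88 ± 0.14) rose and 0 fell in Oct4 E9.5 (4 and 0 adjusted over the list alone). The heart list had adjusted p = 0.000454, and adjusted p = 0.446 with an estimated correlation. Of 19 hypoxia and glycolysis genes 6 rose, with Bnip3 at 0.44 ± 0.06, and 0 fell (11 higher adjusted over the list alone). The hypoxia list had adjusted p = 0.000898, and adjusted p = 0.446 with an estimated correlation. Of 12 primed epiblast genes 4 rose, among them Dnmt3b, Sfrp2 and Pim2 (1.52 ± 0.11), and Zic5 and Lin28b (-0.31) fell (5 and 2 adjusted over the list alone). The primed epiblast list had adjusted p = 0.0032, and adjusted p = 0.147 with an estimated correlation. Of 17 paraxial mesoderm genes 5 rose, Meox1, Aldh1a2 (0.51 ± 0.07), Tcf15, Dll3 and Hes7 (6 higher and 2 lower adjusted over the list alone). The somite list had adjusted p = 0.0244, and adjusted p = 0.479 with an estimated correlation. Without 1 library Hand2, Dnmt3b and Tcf15 had up to 0.121, 0.127 and 0.0932 (control 2), and Zic5, Hes7 and Dll3 up to 0.225, 0.161 and 0.0676 (induced 5). The primed epiblast and paraxial mesoderm list calls were lost with limma-voom, and the latter with a GC offset (0.0537). Of 13 mitochondrially encoded genes 6 fell and 0 rose (7 lower adjusted over the list alone), with mt-Co1 at -0.11 ± 0.03 (0.0761 without control 2). The mitochondrial list had adjusted p = 0.0195, and adjusted p = 0.488 with an estimated correlation. With a GC offset this list had 0.781 and none of the 6 was called.

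Lists that did not pass in Oct4 E9.5 held further single calls. Of 12 node and endoderm genes Lefty1 (0.0750 to 2.45 CPM, 5.10 ± 0.56) and Lefty2 were higher and Nkx2-1, Foxa2 and Shh lower (2 and 3 adjusted over the list alone, adjusted p = 0.595). Of 14 retinoic acid genes Cyp26a1, Cyp26c1, Rarg and Aldh1a2 were higher and Aldh1a3, Cyp26b1 and Crabp2 lower (6 and 4 adjusted over the list alone, adjusted p = 0.766). Of 16 neural crest genes Sox10 was higher and 4, among them Dlx1, Dlx2 and Alx4, lower (3 and 4 adjusted over the list alone, adjusted p = 0.388). Of 19 integrated stress response genes Ddit4 was higher and Psat1, Phgdh, Mthfd2, Aldh18a1 and Slc7a11 lower (1 and 6 adjusted over the list alone, adjusted p = 0.164, and 0.047 with a GC offset). Calls kept in every fit without 1 library numbered 4 of 5, 4 of 7, 3 of 5 and 4 of 6 in these 4 lists. Parietal endoderm (10 tested, Lamb1 higher, Lama1 and Nid1 lower, 1 and 2 adjusted over the list alone, adjusted p = 0.586) kept 2 of 3 calls, and trophoblast (6 tested, Ets2 higher, Wnt7b lower, 2 and 1 adjusted over the list alone, adjusted p = 0.949) kept both. Cell cycle genes (27 tested, Mki67, Kif11 and Rrm2 lower, 0 and 3 adjusted over the list alone, adjusted p = 0.0907) kept 1 of 3. None of the calls was kept in every such fit for Wnt feedback (Notum and Dkk1 higher of 10, 4 and 1 adjusted over the list alone, adjusted p = 0.104) and visceral endoderm (Rbp4 and Apoa1 higher of 10, 2 and 0 adjusted over the list alone, 0.322). The same held for core pluripotency (Sall4 higher of 9, 2 and 1 adjusted over the list alone, adjusted p = 0.0782) and p53 targets (Pmaip1 higher of 18, 1 and 0 adjusted over the list alone, 0.0951). It also held for the immediate early (Egr1 higher of 9, 1 and 0 adjusted over the list alone, adjusted p = 0.595) and nuclear respiratory chain lists (Atp5c1 lower of 25, 0 and 0 adjusted over the list alone, 0.595). With edgeR 0 of 16 endothelial (adjusted p = 0.507) and 0 of 5 primordial germ cell (adjusted p = 0.552) genes were called.

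Nanog induction at E9.5 gave a lower primitive haematopoiesis list, a call lost with an estimated correlation (adjusted p = 0.225), and higher Trh. The lymphoid and erythroid factor gene Ikzf1 fell from 11.2 to 3.26 CPM (log2 -1.74 ± 0.20), the anion exchanger Slc4a1 from 124 to 51.0 CPM (-1.26 ± 0.13) and the erythroid spectrin Spna1 from 32.4 to 9.99 CPM (-1.67 ± 0.14). Lower too were Hemgn (-1.59 ± 0.17), the red cell pyruvate kinase gene Pklr (-1.89 ± 0.19) and Acp5 (-1.77 ± 0.21). Trh, the thyrotropin-releasing hormone gene, rose from 6.81 to 22.2 CPM (1.74 ± 0.17, adjusted p = 4.66e-06) and Selenbp1 by 2.71 ± 0.27. The edgeR test called 3772 of 13305 genes, 2045 higher and 1727 lower, of which 114 and 73 changed by at least 2-fold. Fold changes followed GC content (Pearson r = 0.534 across genes, which are not independent replicates). With a GC offset 1097 genes were called (752 shared), 497 higher and 600 lower, against the Oct4 line controls 390 (252 shared), with DESeq2 2348, with 1 model over all libraries 1958, and without control 2 or control 3 1482 or 2161. Of the 24 genes named by size, 20 kept their call in every fit without 1 library and 11 in every setting tried.

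Of 24 primitive haematopoiesis genes 13 fell and Gata2 rose in Nanog E9.5 (1 and 14 adjusted over the list alone). The haematopoiesis list had a median log2 fold change of -0.816, adjusted p = 1.11e-10, and adjusted p = 0.225 with an estimated correlation. With a GC offset the median was -1.2 and against the Oct4 line controls -1.2, and 10 of the 13 lower genes were called in both; Gata2 turned sign against the Oct4 line controls. Klf1 (-1.27 ± 0.24) and Gata1 (8.17 to 3.65 CPM, -1.14 ± 0.22) kept their call in every setting. The embryonic globins Hbb-bh1 (1892 ± 301 to 397 ± 79.7 CPM, -2.22 ± 0.23) and Hbb-y (2118 to 559 CPM, -1.89 ± 0.24) lost it without induced 1 (0.0525 and 0.0731). The adult globins Hbb-b1 (17.4 to 51.6 CPM, 1.59 ± 0.10) and Hbb-b2 (1.15) rose, 2 of 3 maternal blood genes (2 adjusted over the list alone), and Hbb-b1 lost its call against the Oct4 line controls (0.249). The maternal blood list had adjusted p = 3.3e-06, and adjusted p = 0.139 with an estimated correlation. All 13 mitochondrially encoded genes fell (13 adjusted over the list alone), with mt-Co1 from 6647 to 5164 CPM. The mitochondrial list had adjusted p = 2.87e-10, and adjusted p = 0.316 with an estimated correlation. The list lost its call with a GC offset (0.507) and against the Oct4 line controls (0.502).

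Of 10 Wnt feedback targets 5 rose and 0 fell in Nanog E9.5 (9 higher adjusted over the list alone): Axin2 by 0.42 ± 0.08, Lef1, Lgr5 (0.80), Znrf3 and Sp5, of which Lgr5 kept its call in every setting, Lef1 lost it without control 3 (0.132) and Znrf3 without control 2 (0.276). The Wnt feedback list had adjusted p = 0.000912, and adjusted p = 0.213 with an estimated correlation, and 0.105 against the Oct4 line controls. Of 35 Hox genes 12 rose and 0 fell (12 adjusted over the list alone), such as Hoxb5 (0.89 ± 0.19) and Hoxd3 (0.48 ± 0.08). Of the 12, 3 were called with a GC offset and 0 against the Oct4 line controls. The Hox list had adjusted p = 0.00138, and adjusted p = 0.504 with an estimated correlation. Of 19 neuronal genes 5 fell and 0 rose, Stmn2 (-0.83 ± 0.17), Nhlh2, Neurod4, Elavl4 and Dcx (5 adjusted over the list alone), with 0.145 for Dcx without control 3 and 0.155 for Elavl4 without induced 2. The neuronal list had adjusted p = 0.0112, and adjusted p = 0.632 with an estimated correlation. Of 14 anterior neural genes 5 fell, with Pax6 from 62.8 to 37.2 CPM (-0.72 ± 0.09) and Emx2 at -0.81, and 0 rose (5 adjusted over the list alone). The anterior neural list had adjusted p = 0.0225, and adjusted p = 0.593 with an estimated correlation. Of 27 cell cycle genes 3 rose and 12 fell (3 and 12 adjusted over the list alone), with Bub1 from 240.0 to 176 CPM and Cenpf by -0.41. With a GC offset the list had 0.0537, and against the Oct4 line controls its direction turned (0.948). The cell cycle list had adjusted p = 0.0032, and adjusted p = 0.173 with an estimated correlation. Of 19 hypoxia and glycolysis genes 7 rose, with Aldoa at 0.41 ± 0.07, and 0 fell (7 and 1 adjusted over the list alone). The hypoxia list had adjusted p = 0.0305, and adjusted p = 0.632 with an estimated correlation, 0.0573 with a GC offset and 0.0636 against the Oct4 line controls.

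Among lists that did not pass in Nanog E9.5, Sox10, a neural crest factor (11.8 to 23.1 CPM), rose and Sox2, a neural and pluripotency factor (-0.47), fell in every setting. Sox10, Foxd3, Dlx2, Erbb3 and Prrx2 were higher and Prrx1 lower of 16 neural crest genes (5 and 1 adjusted over the list alone, adjusted p = 0.232), and Sox2 lower of 7 core pluripotency genes (0 and 1 adjusted over the list alone, adjusted p = 0.919). Of 16 endothelial genes Tie1, Flt4, Cldn5, Sox18 and Plvap were higher and Emcn lower (5 and 1 adjusted over the list alone, adjusted p = 0.0534). Of 10 parietal endoderm genes Pth1r, Lamb1, Lama1, Col4a1 and Col4a2 were higher and Nid1 lower (5 and 1 adjusted over the list alone, adjusted p = 0.0782). Of 16 streak genes 6 were higher and Nkx1-2 lower (7 and 1 adjusted over the list alone, adjusted p = 0.0832). Calls kept in every fit without 1 library numbered 1 of 6 in neural crest, 3 of 6 in endothelium, 1 of 6 in parietal endoderm and 1 of 7 in streak. The endothelium, streak and p53 lists had 0 members called with a GC offset, and against the Oct4 line controls 0 of the endothelium, parietal endoderm, stress response and nuclear respiratory chain lists. Of 18 stress response genes Phgdh, Shmt2, Sesn2, Ddit4 and Pck2 were higher (5 and 0 adjusted over the list alone, adjusted p = 0.123, 3 kept), and of 10 immediate early genes Jun, Junb and Ier2 were higher and Klf6 lower (3 and 1 adjusted over the list alone, adjusted p = 0.164, 2 kept). Of 18 p53 targets Bbc3, Bax, Sesn2 and Phlda3 were higher and Ccng1 and Trp53inp1 lower (4 and 2 adjusted over the list alone, adjusted p = 0.805, 3 kept). Of 14 retinoic acid genes 3, among them Rara and Rarg, were higher and Cyp26b1, Rarb and Aldh1a3 lower (3 and 4 adjusted over the list alone, adjusted p = 0.789, 3 kept); with a GC offset the list passed (0.00243), with 0 higher and 4 lower. Of 25 nuclear respiratory chain genes Ndufv1, Uqcrc1 and Cyc1 were higher and Ndufa4, Uqcrc2, Cox5a and Cox7a2 lower (4 and 4 adjusted over the list alone, adjusted p = 0.555, and 0.0339 with a GC offset, 1 kept). Of 16 paraxial mesoderm genes Tcf15, Foxc2 and Uncx were higher and Pax3 and Foxc1 lower (4 and 3 adjusted over the list alone, adjusted p = 0.565, 1 kept). Of 12 primed epiblast genes Dnmt3b, Sox3 and Foxd3 were higher and Otx2, Zic5 and Lin28b lower (4 and 3 adjusted over the list alone, adjusted p = 0.91, 1 kept). Of 24 heart genes Nkx2-5 and Hand1 were higher and Nppb lower (1 and 1 adjusted over the list alone, adjusted p = 0.586, 0 kept). Trh was the called gene of 10 in the node list (1 and 0 adjusted over the list alone, adjusted p = 0.178), Tcfap2c of 5 germ cell genes (1 and 0 adjusted over the list alone, adjusted p = 0.595) and Lrp2 of 6 visceral endoderm genes (0 and 0 adjusted over the list alone, adjusted p = 0.949). Without 1 library Tcfap2c had 0.0601 and Lrp2 0.306. With edgeR 0 of 6 trophoblast genes were called (adjusted p = 0.855). With a GC offset Bax, Sox3, Uqcrc1, Prrx2, Col4a2, Pth1r, Cyc1, Phgdh and Rarg turned sign, and against the Oct4 line controls Plvap, Sox18, Emcn, Sox3, Dlx2, Tcf15, Pth1r, Phgdh, Bbc3, Trp53inp1 and Hand1 did.

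Oct4 and Nanog induction moved many of the same genes at E7.5. Of 14049 genes tested in both, 130 rose in both (9.56 for independent lists of 326 and 412, Fisher's exact p = 1.53e-117, one-sided), among them Eomes, Fgf5 and Nodal. In both 262 fell (26.3 for 550 and 672, exact p = 3.04e-211), among them Hbb-bh1, Meox1 and Tbx4, while 1 and 2 genes went opposite ways. The fold changes had a Pearson r of 0.482 across genes, which are not independent replicates. The test of the difference between lines called 34 of 16680 genes at E7.5, 23 with the higher fold change for Oct4 and 11 for Nanog, among them Pcdh12, a protocadherin gene of endothelium and placenta (-4.01 ± 0.67, adjusted p = 0.0331), and mt-Te (8.52 ± 0.53). The call of Pcdh12 was lost in 9 of 11 fits without 1 library (up to 0.189 without Nanog control 2), with limma-voom (0.291) and among long protein-coding models (0.0594). It called 241 with DESeq2, 19 with limma-voom, 56 without a filter and 6 among long protein-coding models. Left-out libraries gave 19, 16 or 102 without Nanog control 2, control 3 or induced 1 and 19, 19 or 20 without Oct4 control 1, control 3 or induced 3. Visceral endoderm genes differed between lines (median difference 0.743, adjusted p = 3.53e-17, adjusted p = 0.122 with an estimated correlation). The mitochondrially encoded list (-0.99, adjusted p = 3.09e-17, adjusted p = 0.141 with an estimated correlation) and the somite list (0.575, adjusted p = 0.000378, adjusted p = 0.122 with an estimated correlation) differed too. The trophoblast list (-1.8, adjusted p = 8.1e-06, adjusted p = 0.347 with an estimated correlation) and the endothelium list (-0.615, adjusted p = 0.000152, adjusted p = 0.176 with an estimated correlation) differed the other way from visceral endoderm.

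At E9.5 more genes were called as different between the inductions, but the test was also more sensitive there. The median absolute log2 difference was 0.206 at E7.5 and 0.216 at E9.5. In simulated data 10.4% and 43.3% of 1.5-fold differences were recovered. The interaction called 1970 of 14604 genes, 813 with the higher fold change for Oct4 and 1157 for Nanog, and 744 with a GC offset, 837 without Nanog control 2 and 1265 without Oct4 induced 3. The primitive haematopoiesis list differed between the inductions (Oct4 minus Nanog, median difference 1.26, adjusted p = 1.34e-23, adjusted p = 0.0251 with an estimated correlation), as for Spna1 (0.42 and -1.67 for Oct4 and Nanog). Of 13244 genes 203 rose in both (93.7 for independent lists, exact p = 1.13e-29, one-sided) and 208 fell in both (82.7, exact p = 4.97e-40), among the latter Nr2e1 (-2.25 and -0.94), Aldh1a3 (-1.96 and -0.66) and Dmbx1 (-2.12 and -0.75). With a GC offset 48 and 98 were shared (18.8 and 27 for independent lists), and 48 and 41 genes went opposite ways without it.

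The Oct4 response differed between stages for 1094 of 16359 genes, 791 with the higher fold change at E9.5. Genes that fell at E7.5 and rose at E9.5 included Wnt8a (-1.47 and 4.89), Cdx1 (-3.63 and 2.58), Msgn1 (-3.23 and 2.83) and Aldh1a2 (-4.16 and 0.51), within 107 genes with this pattern (26.3 for independent lists). The Hox (median difference 3.24, adjusted p = 0.00157 with an estimated correlation), primitive haematopoiesis (1.83, 0.00996), endothelium (0.855, 0.0123) and heart (0.94, 0.0251) lists differed. Shh fell at both stages (-3.80 and -0.73), one of 60 genes (24.9 for independent lists), and Lefty1 rose at both (4.29 and 5.10), one of 45 (12.2). Another 26 rose, then fell (11.6), so every direction was in excess. The Nanog response differed between stages for 1907 of 14897 genes, 1194 with the higher fold change at E9.5. It differed for fewer without any 1 control, and for 1192 without E9.5 induced 2. The primed epiblast (-1.04, adjusted p = 0.0181 with an estimated correlation), Hox (2.56, 0.0181) and somite (1.43, 0.0197) lists differed. Ikzf1 (-2.19 and -1.74) and Hbb-bh1 (-6.04 and -2.22) fell at both stages, among 59 genes (80.4 for independent lists), or 48 with a GC offset (32.8). Without it 138 fell, then rose (95.9).

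Controls changed widely between E7.5 and E9.5: 11595 of 15770 genes differed in the Oct4 line and 9493 of 14872 in the Nanog line. In the Oct4 line Slc4a1 rose from 0.0555 to 129 CPM and the neuronal factor gene Neurod4 at least 486-fold. Apoc2, an apolipoprotein gene (chr 7, 20256928 to 20266772), fell from 519.8 to 0.171 CPM (-11.38 ± 0.17, adjusted p = 9.11e-12). In the Nanog line Hbb-y rose by 11.61 ± 0.51 and Apoc2 fell from 310.0 to 0.370 CPM (-9.70 ± 0.12). Set against the stage difference of the other line's controls, 602 of 909 called genes (66.2%) of Oct4 E7.5 moved toward the younger stage, 663 of 1077 (61.6%) of Nanog E7.5, 931 of 1275 (73%) of Oct4 E9.5 and 1713 of 3765 (45.5%) of Nanog E9.5. Of all genes 59.2%, 57.1%, 57.5% and 48.5% did. Pearson r across genes was -0.165, -0.0476, -0.235 and -0.0474. It was 0.0369 for Nanog E7.5 against its own line, whose controls are shared, and -0.258 for Nanog E9.5.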

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

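The interaction tests were planned, whereas the tests of explanations for the 3 patterns below were chosen only after the result was seen, as were the counts of called members with long models and of splits that part all pairs in the stage difference; the bounds of the former were written before each was run, except for the correlation between lines at E7.5, whose value was known.

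The response to Oct4 and to Nanog differed at E7.5 for 34 genes, with log2 differences (Oct4 minus Nanog) of 8.516 for mt-Te, 10.19 for mt-Ts1, 10.68 for Hspe1-ps6, -4.01 for Pcdh12 and 7.996 for mt-Tg, for 2 of 33 genes named by size and for 9 of 26 lists. Of these 5 genes 3 are mitochondrial tRNA models and Hspe1-ps6 is a pseudogene, whose reads are uncertain. At E9.5 the responses differed for 1970 genes, 42 of 48 genes named by size and 11 lists: Pou5f1 8.046, Rpl15-ps2 -7.186, Rps26-ps1 -7.396, Rpl10-ps3 -12.42, Tpm3-rs7 6.862 and the primitive haematopoiesis list with a median of 1.26. The Oct4 response differed between stages (E9.5 minus E7.5) for 1094 genes, 28 of 46 named genes and 13 lists: Pou5f1 7.008, Hes3 8.701, Hbb-bh1 6.424, Hoxc5 6.58, Hoxc10 6.437, and list medians of 1.83 for primitive haematopoiesis, 0.855 for endothelium, 3.24 for Hox and 0.94 for heart. The Nanog response differed between stages for 1907 genes, 26 of 47 named genes and 12 lists: Rpl10-ps3 11.85, Hspa14 7.03, B3gnt3 -7.805, Eif5al3-ps 10.19, and list medians of -1.04 for primed epiblast, 2.56 for Hox and 1.43 for somite. Genes named by size were chosen as extreme in these libraries, which raises their shares. Pou5f1 counts hold the transgene. Without 1 library, calls of the Nanog stage difference were lost for B3gnt3 (Nanog E9.5 control 3), Eif5al3-ps (Nanog E9.5 induced 3) and Hspa14 (Nanog E7.5 control 3). Between lines they were lost for Pcdh12 and Hspe1-ps6 (Nanog E7.5 control 2), mt-Tg (Nanog E7.5 control 3), Tpm3-rs7 (Nanog E9.5 control 2) and Rps26-ps1 (0.0639, Oct4 E9.5 control 2). With an estimated correlation 0, 1, 4 and 3 lists passed in these 4 tests, and the medians given are of those that did. These tests fit 10 to 12 libraries and the inductions 5 or 6, so their numbers of passing lists are not comparable. Fitted values of genes at 0 in a group depend on the fit and are not bounds.

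The split of the pools by doxycycline called 991 genes in Oct4 E7.5, 1 of 10 splits, and the highest other split called 1. It called 1297 in Oct4 E9.5, 1 of 10, with 4 for the highest other split. The split of the Oct4 line controls by stage called 11595, 1 of 10, with 0 for the highest other. In these 3 cases 10 splits are too few for a share under 0.05. In Oct4 E7.5 the numbers were taken as possible pairs, and the 3 other splits that part all 3 pairs called 0. The fits of the splits have no replicate block. For the Oct4 stage difference, 1 of 100 splits called as many as 1094 and the highest other called 528. Of these 100, 38 part all 3 pairs of Oct4 E7.5. Among the 38 the real one was again alone, with 528 for the highest other, a split that kept the real labels at 1 of the stages. The splits exchange control and induced labels within each stage. A share under 0.05 therefore bears only on chance without an effect of induction at either stage. It cannot exclude chance for the difference between stages.

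In both lines E7.5 induction came with lower Hox, primitive haematopoiesis, somite and heart lists and a higher primed epiblast list, none of which passed with an estimated correlation (adjusted p = 0.0685 to 0.251). Reads of short models or pseudogenes are argued against as the source of the number of calls. With long protein-coding models alone that number was at least 102% of the first in either line. All 68 (Oct4) and 46 (Nanog) called members of these lists are such long models and were called again with the same sign. Their own counts were unchanged in this fit, so it cannot show whether they share reads with pseudogenes. A delay of the induced embryos or younger pools stays open. In Nanog E7.5, the lower share, 61.6% of called genes moved toward the younger stage, between the bounds of 60% and 70%. Of all genes 57.1% did, so these bounds cannot decide. Of its lower genes 56.7% rose with stage. Doxycycline or handling of the mothers, shared by both lines, cannot be told apart from shared targets of both factors, because no group received doxycycline alone and the lines correlated with r = 0.482 across genes. An effect of the induced factors on the epiblast may also account for it and was not tested separately.

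In Nanog E9.5 many small changes came with lower erythroid genes. A GC trend between libraries may account for most of the count, since 29.1% of it was left with a GC offset. So may Nanog line controls that stand apart, since still fewer genes were called against the Oct4 line controls. Both are argued against for the erythroid genes, whose list median was -1.2 in either fit. Depth is argued against as the source of the count, since 75.7% was left in thinned libraries. A lower share or later maturation of red cells, or embryos of another exact age, stays open and was not tested.

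In Nanog E7.5, 12 of 18 visceral endoderm genes fell, and the list did not pass with an estimated correlation (adjusted p = 0.212). A GC trend is argued against (list median -0.935 with the offset), as are controls that stand apart (-1.33 against the Oct4 line controls). The induced libraries stood apart in reads of gene models under 80 nucleotides (0.575 to 1.13 CPM, against 29 to 51.9 CPM in Oct4 E7.5 controls). Both tests keep these induced libraries, so neither can exclude a batch difference that sets them apart. In the same pools the trophoblast list was higher (median 0.773, 1 of 15 members called higher and 1 lower, adjusted p = 0.503 with an estimated correlation). A smaller share of visceral endoderm, for example from dissection, would lower all its members alike and stays open, since 72.2% of the members lay within 0.5 of the list median, between the bounds of 50% and 80% written before that test was run. A change of expression within these cells could give the same values and was not tested.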

How the results depend on the processing

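Tests planned beforehand and tests chosen only after the result was seen (GC offset, thinned libraries, long protein-coding models, summed symbols, Oct4 line controls, and the block in lists and interactions) are given together. Depth of 4.72 to 42.3 M counts and 2 or 3 pools per group limit the calls, and 1 model over all libraries shares its dispersion between stages. Where a value moved, the cause was not tested.

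Oct4 E7.5 (991 genes) gave 1638 with 1 model over all 22 libraries and 438 to 1101 without 1 library. Nanog E7.5 (1099) gave 1721 without a filter, 2737 with 1 model, 3744 against the Oct4 line controls and 161 to 1383 without 1 library. Oct4 E9.5 (1297) gave 599 with DESeq2, 312 with 1 model and 625 to 1290 without 1 library. Nanog E9.5 (3772) gave 2348 with DESeq2, 1958 with 1 model, 1097 with a GC offset, 390 against the Oct4 line controls and 1482 to 3487 without 1 library. Oct4 against Nanog at E7.5 (34) gave 241 with DESeq2, 19 with limma-voom, 56 without a filter, 6 with long protein-coding models and 16 to 102 without 1 library, and at E9.5 (1970) 744 with a GC offset and 837 to 2178 without 1 library. The stage interactions gave 734 to 1361 (Oct4) and 807 to 2376 (Nanog) without 1 library, and the stage comparisons of controls 10706 to 11748 (Oct4 line) and 8253 to 8752 (Nanog line). Other alternatives stayed within 1.5 times the count.

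Of 49 list calls 0 passed with an estimated correlation, which gave the highest adjusted p in 46, and 24 were lost with it alone; fry lost 17, limma-voom 5, the GC offset 5 and the Oct4 line controls 6, with the cell cycle list of Nanog E9.5 reversed (0.948). The GC offset added 6 lists: germ cell (0.0293) and visceral endoderm (0.0284) in Oct4 E7.5, with the replicate block, nuclear respiratory chain in Nanog E7.5 (0.0402) and Nanog E9.5 (0.0339), stress response in Oct4 E9.5 (0.047) and retinoic acid in Nanog E9.5 (0.00243). The overlap at E9.5 was 48 (higher) and 98 (lower) with a GC offset. The alignment with the stage difference was -0.214 (Oct4 E7.5) and -0.151 (Nanog E7.5) by Spearman, turned to 0.00995 for Nanog E9.5 by Spearman and to 0.0369 for Nanog E7.5 against the same line, and was -0.258 for Nanog E9.5 against the same line. Without 1 library it ran from -0.219 to -0.105, -0.0778 to -0.0142, -0.265 to -0.187 and -0.0655 to -0.0223 in Oct4 E7.5, Nanog E7.5, Oct4 E9.5 and Nanog E9.5.

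With the replicate block Oct4 E7.5 gave 1287 genes, Nanog E9.5 3290, the stage comparisons 11406 (Oct4 line) and 9179 (Nanog line), Oct4 against Nanog at E7.5 40, the Oct4 stage interaction 1634 and the lists 52 calls. Nanog E9.5 pools with the same number correlated at -0.0759. Only numbers 2 and 3 are shared there, which gives a single value up to its sign, so this does not decide whether they are pairs. The block lost the call of 4 named genes, Fgf4 in Oct4 E7.5 (adjusted p = 0.0574), Ebf3 in Oct4 E7.5 (0.0521), Ebf2 in Oct4 E7.5 (0.0734) and Otx1 in Oct4 E7.5 (0.0509), and of 23 named genes in Nanog E9.5 (up to 0.251, Pax3). It added the germ cell (0.0286) and visceral endoderm (0.0361) lists in Oct4 E7.5 and the nuclear respiratory chain list (0.0483) in Nanog E7.5 and changed the call of no other named gene or list. Of the 991 genes of Oct4 E7.5 it kept 951. No paired analysis was possible for Nanog E7.5 and Oct4 E9.5 because control and induced pools share only the number 3.

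Named genes lost their call in 714 of 3111 fits without 1 library and in 156 of 529 with 1 model, 68 of 539 with DESeq2 and 32 of 550 with limma-voom. With the GC offset 91 lost it and 10 turned sign, and against the Oct4 line controls 92 and 18; most were in Nanog E9.5 (71 and 10 of 137, 86 and 18 of 135). With 1 model 72 of 119 were lost in Oct4 E9.5 and 78 of 137 in Nanog E9.5. Summed over its models Pou3f1 turned to 1.218 in Nanog E7.5. With the GC offset log2 fold changes turned in Nanog E9.5 for Bax (-0.03552), Pkm2 (-0.02407), Sox3 (-0.2457), Uqcrc1 (-0.05606), Prrx2 (-0.1246), Col4a2 (-0.0301), Pth1r (-0.08053), Cyc1 (-0.1489), Phgdh (-0.02237) and Rarg (-0.01501). Against the Oct4 line controls they turned in Nanog E9.5 for Scand1 (-0.4184), Zfp771 (-0.4349), Plvap (-0.02338), Prr7 (-0.06682), Sox3 (-0.3027), Dlx2 (-0.1138), Snai1 (-0.07125), Tcf15 (-0.1072), Gata2 (-0.02083), Hoxb2 (-0.02416), Rpl10-ps3 (-0.2599), Pth1r (-0.06013), Hand1 (-0.08617), Bbc3 (-0.09992), Emcn (0.04628), Phgdh (-0.01993), Sox18 (-0.0663) and Trp53inp1 (0.03063).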

Other observations

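The following genes were chosen after their values were seen. In Nanog E9.5 no marker of sex passed the test: Xist, of the inactive X chromosome, read 605 ± 60.4 CPM in controls and 1120 ± 223 CPM in induced pools (2 and 3 pools, edgeR adjusted p = 0.0697), and the Y-linked genes Ddx3y 40.4 ± 4.51 and 14.2 ± 11.9 CPM (0.3), Uty 23 and 7.33 CPM (0.268), Kdm5d 38.3 and 12.75 CPM (0.244) and Eif2s3y 32.3 and 9.51 CPM (0.228). Induced pool 2 stood apart with few reads from the Y chromosome (Ddx3y 0.653, Uty 0.327, Kdm5d 1.63 and Eif2s3y 0.653 CPM, against 18.6 and 23.2 CPM of Ddx3y in induced pools 1 and 3). In Oct4 E7.5, control 2 and induced 2, which share their number, had the fewest: Ddx3y 7.15 and 9.03 CPM against 35.5 to 42.6 CPM in the other 4 pools, and Kdm5d 2.94 and 3.00 CPM against 20.4 to 26.1 CPM. In Nanog E7.5 Xist was lower in induced pools (609.9 and 370 CPM, edgeR adjusted p = 0.0416) and Eif2s3y higher (18.2 and 38.6 CPM, 0.0115). In the same pools Ddx3y (29.4 and 50.04 CPM, 0.0653), Uty (15.2 and 22.6 CPM, 0.143) and Kdm5d (16.2 and 21.99 CPM, 0.153) did not pass. These calls were not refitted without single libraries. Sex was not part of any model.

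At E7.5 adult globins were read in all pools. Hbb-b1 read 250.5 ± 26.3 and 111 ± 82.6 CPM in Nanog E7.5 control and induced pools and 120 ± 80.3 and 127 ± 73.3 CPM in Oct4 E7.5, where the embryonic Hba-x read 3.81 and 0.0510 CPM. Single pools ran from 51.7 to 208 and from 82.8 to 212 CPM for Hbb-b1 in Oct4 E7.5 control and induced pools. Adult globins are abundant in blood of the mother. The trophoblast giant cell hormone gene Prl3d1 read 21.1 ± 24 and 80.02 ± 13 CPM in Nanog E7.5 and 17.3 and 5.94 CPM in Oct4 E7.5, and Prss29, a serine protease gene of the uterus, 3.51 and 66.3 CPM in Nanog E7.5 and 0.121 and 0.393 CPM in Oct4 E7.5.

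Over 10040 genes, induced pools of Nanog E9.5 correlated with a mean r of 0.9695 with controls of their own line and 0.9795 with those of the Oct4 line. In the other sets the own controls were closer: 0.9835 and 0.9634 in Oct4 E9.5, 0.9517 and 0.9456 in Nanog E7.5 and 0.9756 and 0.9561 in Oct4 E7.5. The pseudogene Rpl10-ps3 read 0.0308 CPM in Nanog E9.5 controls, 282 ± 173 in their induced pools and 343 and 408 CPM in Oct4 E9.5 controls and induced pools, and mt-Te read 11.7 and 0.014 CPM in Nanog E7.5 controls and induced pools.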
